A study of Homo sapiens with 21 samples.

How the data were processed

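RNA from 21 human skin biopsies, 4 healthy and 17 from MF lesions, was hybridised to the NanoString PanCancer Immune Profiling panel after column extraction of total RNA, per the labels' protocols. The deposited values are a normalized signal per probe and sample. How the authors normalized them is not given in the sources used here, so it was read from the values. In every sample the low gene values lie on multiples of a factor of 0.709 to 1.98, or midway between them, within a tolerance of 0.1 counts for 100% of them. This describes background-subtracted counts times a scaling factor per sample, with values below 1 set to 1. Dividing by that factor gave the gene counts per sample quoted as depth. The geometric mean of 40 housekeeping genes was 438.0 in 18 samples and 322.0 in MF samples 8, 9 and 10, a log2 difference of -0.44, so those 3 were scaled to another level. Control probes are unscaled.

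The value table holds 778 probes: 8 negative controls, 6 positive controls, 40 housekeeping genes and the genes under study. Of these, 1 gene that would tell a donor's sex was left out everywhere, which left 723. The authors' other deposited table gives a mean signal per probe, which equals the mean of the value table within 0.0081 for all 778 shared probes, and it holds 5 further probes. Its 21 columns of samples carry run names that match no sample label and were not used. Its headers name 5 runs, which the names alone do not tie to samples. Its columns were not compared with the labelled samples by their values, so run was not tested as a batch. Its probe classes are shifted against the probe names (14 of 14 control probes are classed as housekeeping and 25 of 40 housekeeping genes are), so classes were taken from the names.

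Values were analysed as log2(value + 1), on which scale fold changes understate the change of weak genes. A gene was tested if it exceeded the detection floor, the mean plus 2 SD of the sample's negative controls times the sample's factor, in at least 4 samples, which kept 715 genes and left out 8. MF was compared with healthy skin in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with no covariates and Benjamini-Hochberg adjustment, threshold 0.05. The unit was not a raw count, so no count model was used. Where no sample of a group exceeded the floor, a fold is a lower bound, with each such sample set to the higher of its floor and its value. Before the data were examined, 27 gene lists, the tests, the alternatives and a rule for named genes were fixed. The rule for named genes takes the 12 largest rises and 12 largest falls past the threshold, up to 3 members of each list with the smallest adjusted p, and every interferon ligand and receptor, 90 genes in all. Genes named outside it are said to be chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and per-sample scores with exact permutation tests over 5985 splits. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

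RefSeq transcripts matched 698 of the 715 tested genes to the GRCh38.p14 gene table, where DDX58 has the current symbol RIGI. The build behind the probes is not given in the sources used here, and no coordinates are printed. No pair of samples was identical. Correlations of log2 values were 0.907 to 0.949 between healthy samples and 0.773 to 0.961 between MF samples.

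The gene test was tested on simulated data with the overall mean and a pooled spread of each of the 715 genes and both group sizes. Spreads that differ between the groups were not simulated. In the data the SD was 0.09 in healthy skin and 0.68 in MF for IFITM1, and 1.26 and 0.73 for EGR1. It recovered 36 of 100 genes changed by 1 on the log2 scale and 76 of 100 changed by 2, all in the right direction, with 5 of 515 unchanged genes called, and it called 0 genes when nothing was changed. With simulated independent genes and nothing moved, camera and the score test each passed 0 of 27 lists. In the data the genes of a list are correlated, by an estimated 0.093 for Th17 genes to 0.75 for T cell markers. The simulation therefore cannot show how camera at its preset correlation behaves on them.

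Alternatives were centring on housekeeping genes or on the median gene, quantile normalization, no filter or a filter of values above 50 in 4 samples, a pseudocount of 10, array weights, a trended robust variance, the replicate number as a block, an exact Mann-Whitney test and leaving out each sample. With the block, only MF samples that share a number with a healthy sample bear on the comparison. Added after seeing the data were leaving out MF samples 8, 9 and 10, setting values below 20 to 20, a positive control covariate, and subtracting each sample's median over probes of genes of other organs.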

Results

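Transcripts of immune and tumour-associated genes were counted with a NanoString panel, an assay in which colour-coded probes are hybridised to RNA and counted without amplification, in 21 human skin biopsies. Healthy skin from plastic surgery gave 4 samples, and lesions of mycosis fungoides (MF), a lymphoma of skin-homing T cells, gave 17. The labels place every MF biopsy in untreated lesional skin. The series' design text speaks instead of 9 patients sampled before and after PUVA phototherapy, so it does not match the labels, and the labels were followed. If MF samples share a patient or include treated lesions, the labels do not show it, and every test here treats the samples as independent. The gene counts recovered per sample, after the authors' background subtraction, ranged from 404237 to 703631 in healthy skin and from 453033 to 1844570 in MF. Of 723 panel genes, 685 to 704 lay above the detection floor in a healthy sample and 603 to 700 in an MF sample. The labels name separate samples and nothing more, so p-values measure the spread between these samples.

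The comparison asks how immune genes, and the type I interferon system named in the series title, differ between MF lesions, labelled as untreated, and healthy skin. In MF 14 of 15 T cell markers, 11 of 16 cytotoxic genes and 12 of 20 macrophage markers were higher, and 2 macrophage markers were lower. These lists passed the camera test at its preset correlation (adjusted p = 0.665 with an estimated correlation for each). The largest rise was that of CCL18, a chemokine of alternatively activated macrophages. It rose from a geometric mean of 109.9 normalized counts in 4 healthy samples to 7604 in 17 MF samples (log2 fold change 6.10 ± 0.91 SE, limma adjusted p = 0.000313). Of 17 interferon-stimulated genes 9 rose, or 5 with median centring or quantile normalization, among them IFITM1, a membrane protein that blocks virus entry, by 1.86 ± 0.36 on the log2 scale (adjusted p = 0.665 for the list with an estimated correlation). Of 8 type I and III interferon ligands 7 fell, in a list at adjusted p = 0.665 with an estimated correlation. IFNA8 fell by 2.65 ± 0.63 on the log2 scale, from 54.2 to 7.80 normalized counts. It lay above the detection floor in 8 of 17 MF samples. The fall was not particular to the ligands: of 27 cancer-testis genes, normally silent in skin, 21 were lower and 1 was higher. FOS and EGR1, transcription factors induced within minutes of stimulation, fell by 3.92 ± 0.91 and 3.65 ± 0.46 on the log2 scale.

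Of 715 genes tested, 246 changed at an adjusted p under 0.05 in limma, 147 higher and 99 lower in MF, and 340 passed at an unadjusted p under 0.05. At least a 2-fold change was fitted for 136 of the higher and 91 of the lower genes. In 58 of the 715 tested genes no MF value overlapped the healthy range, which chance gives for 0.0334% of genes. The median log2 fold change of all tested genes was 0.21. It moved to -0.50 when each sample was centred on its median gene and to -0.16 with quantile normalization. Higher genes made up 59.8% of those changed with the deposited scaling, 31.0% with median centring and 46.0% with quantile normalization. Without healthy sample 4 the number of lower genes was 61.

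**Figure D1:**
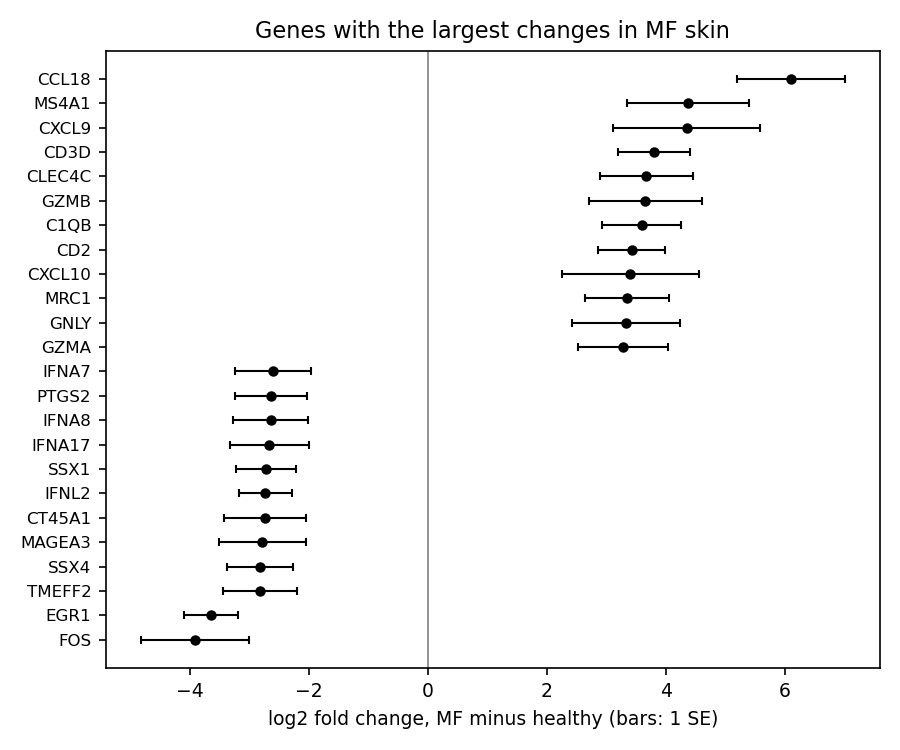
Fitted log2 fold change, MF minus healthy, of the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold (points, with bars of 1 SE; 4 healthy and 17 MF samples). CCL18 stands highest at 6.10 and FOS lowest at -3.92; the value of MS4A1 is fitted against healthy samples that all lie under the detection floor.

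Of the 10 measured type I and III interferon ligands and receptors, 7 fell, none rose and 3 did not pass, and 7 fell when adjusted over the list alone. The list's median log2 fold change was -2.23 (camera adjusted p = 0.000741; adjusted p = 0.665 with an estimated correlation). Its size depends on the lowest values: it was -1.06 with values below 20 set to 20 and -1.43 with a pseudocount of 10, with 7 ligands lower in each. IFNL2 fell by 2.74 ± 0.45 on the log2 scale, IFNA17 by 2.67 ± 0.66, IFNA7 by 2.61 ± 0.64, IFNA1 by 2.33 ± 0.58, IFNB1 by 2.12 ± 0.62 and IFNA2 by 2.04 ± 0.52. The log2 fold changes that did not pass were -0.63 ± 0.64 for IFNL1, 0.10 ± 0.33 for the receptor chain IFNAR1 and 0.91 ± 0.54 for IFNAR2. IFNAR1 turned negative with median centring and quantile normalization and without healthy sample 1 (-0.17), and IFNL1 turned positive with quantile normalization (0.046) and with the other-organ background (0.96). IFNB1 and IFNA2 each lost their call in 1 alternative, with adjusted p from 4.67e-05 to 0.0584 (replicate block) and from 5.28e-05 to 0.08 (other-organ background). All ligand probes lay above the detection floor in 4 of 4 healthy samples. In MF, IFNA1 did so in 6 of 17 samples, IFNA8 and IFNL2 in 8, IFNA2 and IFNB1 in 10, IFNL1 in 13, IFNA17 in 15 and IFNA7 in 16. The interferon alpha genes are close copies, so their probes cannot be taken as separate measurements. With a filter of values above 50 in at least 4 samples, which tests 2 ligands and both receptors, those ligands were still lower, but the list's median was -1.26 and it no longer passed (camera adjusted p = 0.123). Over all alternatives the list's adjusted p ran from 2.05e-05 to 0.665. Probes of cancer-testis genes, normally silent in skin, moved with them: 21 of 27 fell and 1 rose (22 lower and 1 higher adjusted over the list alone), with a median of -1.95 (camera adjusted p = 2.55e-10; adjusted p = 0.351 with an estimated correlation). The number lower was 9 with the other-organ background subtracted, 4 with values above 50, and 15 without healthy sample 4 or with values below 20 set to 20. SSX4 fell by 2.82 ± 0.55, MAGEA3 by 2.78 ± 0.73 and ROPN1 by 2.04 ± 0.32 on the log2 scale, while CTAG1B, chosen after its values were seen, was at least 1.27-fold higher. MAGEA3 stood at 222.9 normalized counts in MF sample 17, above the highest healthy value of 96.1, against 1.25 to 24.8 in the other MF samples. Of the 99 lower genes, 65 had a geometric mean under 100 normalized counts in healthy skin.

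**Figure D2:**
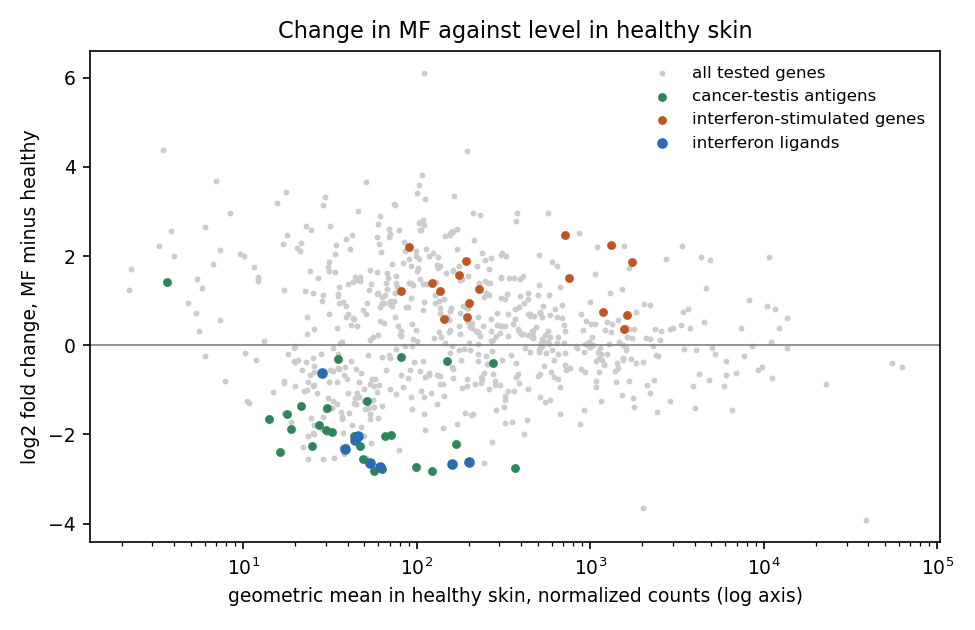
Log2 fold change, MF minus healthy, of each of the 715 tested genes against its geometric mean in healthy skin in normalized counts (log axis), with interferon ligands, cancer-testis antigens and interferon-stimulated genes in colour. The ligands lie at negative changes, from -0.63 for IFNL1 to -2.74 for IFNL2, and the interferon-stimulated genes above 0 with the deposited scaling.

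Of 17 interferon-stimulated genes, 9 rose and none fell, and 12 rose when adjusted over the list alone (median log2 fold change 1.26, camera adjusted p = 0.000682; adjusted p = 0.665 with an estimated correlation). IFITM1 was above the highest healthy sample in 17 of 17 MF samples, and IFI27 rose by 2.25 ± 0.51 on the log2 scale. The number higher ran from 5 with median centring, quantile normalization or the replicate block to 15 with array weights. Of 13 genes of the type II interferon response, 9 rose and 10 did so when adjusted over the list alone (median 1.96, camera adjusted p = 0.000725; adjusted p = 0.665 with an estimated correlation). CXCL9, a chemokine induced by interferon gamma, rose by 4.35 ± 1.24 and the peptide transporter TAP1 by 1.52 ± 0.36 (adjusted p from 2.45e-06 to 0.056 over the alternatives, highest with the replicate block). CXCL10 rose by 3.40 ± 1.15 (limma adjusted p = 0.0253), and its adjusted p was 0.0604 without healthy sample 2, 0.0842 without healthy sample 3, 0.0735 without healthy sample 4 and 0.0625 with the positive control covariate. Over all alternatives it ran from 0.000126 to 0.0842. Of 21 nucleic acid sensors and interferon inducers, 3 rose and 1, the adaptor TICAM1, fell, and none passed when adjusted over the list alone (median 0.33, camera adjusted p = 0.363). TICAM1 was chosen after its values were seen.

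Of the T cell markers 14 of 15 were higher, and all 15 when adjusted over the list alone (median 2.58, camera adjusted p = 2.99e-07; adjusted p = 0.665 with an estimated correlation). CD3D, a chain of the T cell receptor complex, rose by 3.80 ± 0.61 on the log2 scale and was above the highest healthy sample in 17 of 17 MF samples, as were CD2 at 3.43 ± 0.56 and CD3E at 3.17 ± 0.58. Of 16 cytotoxic effector genes 11 rose, 12 adjusted over the list alone (median 2.29, camera adjusted p = 0.00074; adjusted p = 0.665 with an estimated correlation), including the granule proteases GZMB at 3.66 ± 0.95 and GZMA at 3.28 ± 0.76 and the pore-forming PRF1 at 2.73 ± 0.69. The adjusted p of PRF1 ran from 3.27e-06 to 0.067 over the alternatives, highest with the replicate block. Of 21 checkpoint and costimulatory genes 10 rose, 11 adjusted over the list alone (median 1.52, camera adjusted p = 0.00434; adjusted p = 0.665 with an estimated correlation); the inhibitory receptor LAG3 rose by 3.19 ± 0.61 and TIGIT by 2.42 ± 0.63. The adjusted p of TIGIT ran from 1.01e-05 to 0.0526, highest with the replicate block. Among 23 genes linked to MF in earlier work, 4 rose, and the same number adjusted over the list alone (median 1.5, camera adjusted p = 0.0172; adjusted p = 0.665 with an estimated correlation), with CCL18 among them. The others were the cytokine receptor chain IL2RG at 2.97 ± 0.53, GNLY at 3.33 ± 0.91 and JAK3, the last chosen after its values were seen.

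Of 20 monocyte and macrophage markers 12 rose and 2 fell, 13 and 2 adjusted over the list alone (median 1.63, camera adjusted p = 0.00113; adjusted p = 0.665 with an estimated correlation). The complement component C1QB, made by tissue macrophages, rose by 3.59 ± 0.67 and the mannose receptor MRC1 by 3.35 ± 0.70, while APOE and FCGR1A, chosen after their values were seen, were the members that fell. Of 25 antigen processing and presentation genes 12 rose, 13 adjusted over the list alone (median 1.12, camera adjusted p = 0.00038; adjusted p = 0.665 with an estimated correlation), such as the protease CTSS at 2.51 ± 0.54 and HLA-DPA1 at 2.23 ± 0.49. Of 31 chemokines and receptors 8 rose, and 8 adjusted over the list alone (median 0.97, or 0.92 with genes at their bounds, camera adjusted p = 0.0234; adjusted p = 0.665 with an estimated correlation), including CCL5 at 3.15 ± 0.58 and CCL13 at 2.96 ± 0.74. Of 9 plasmacytoid dendritic cell markers 3 rose, 4 adjusted over the list alone (median 0.85, camera adjusted p = 0.174), among them CLEC4C, a surface lectin of these interferon-producing cells, at 3.67 ± 0.78. CLEC4C lay above the detection floor in 2 of 4 healthy samples, so the size of its rise rests in part on values under the floor. The others were GZMB, also counted as a cytotoxic gene, and IRF8. The limma adjusted p of IRF8 ran from 7.79e-05 to 0.108 over the alternatives. B cell and plasma cell markers gave 3 higher and 1 lower of 17, the same counts adjusted over the list alone (median 0.25, also with genes at their bounds, camera adjusted p = 0.772). The B cell antigen MS4A1 lay above the detection floor in 16 of 17 MF samples and 0 of 4 healthy samples and was at least 9.44-fold higher in MF (limma adjusted p = 0.00373, and 0.0607 with values below 20 set to 20, the highest of its alternatives, which began at 1.89e-06). CD79A, chosen after its values were seen, was another that rose.

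The remaining lists did not pass the camera test with the deposited scaling, and 13 lists in place of 11 passed with quantile normalization, the replicate block or the other-organ background. Passing in some alternative were the Th1 and plasmacytoid dendritic cell lists (quantile normalization, and Th1 with the other-organ background), the keratinocyte list (values above 50, replicate block, other-organ background), the proliferation list (replicate block) and the stromal list (other-organ background). The medians of the sensing, regulatory T cell, B cell and stromal lists turned negative with median centring. The Th1 list had 2 of 13 members higher, also adjusted over the list alone (median 0.97, camera adjusted p = 0.304), with the chemokine receptor CXCR3 at 2.68 ± 0.68. The Th2 list had 3 of 18 lower, 2 adjusted over the list alone (median -0.46, camera adjusted p = 0.303), and IL5 fell by 2.43 ± 0.62. The Th17 list had 1 of 15 lower, also adjusted over the list alone (median -0.83, camera adjusted p = 0.303), which was IL17F at -2.52 ± 0.69. Of 7 regulatory T cell genes none passed, over all genes or adjusted over the list alone (median 0.62, camera adjusted p = 0.363). Natural killer cell markers had 1 higher and 1 lower of 11, also adjusted over the list alone, and their median of -0.51 and mean of 0.22 differed in sign (camera adjusted p = 0.617). Dendritic and Langerhans cell markers had 3 higher and 2 lower of 19, also adjusted over the list alone (median 0.89, camera adjusted p = 0.286), and the lower ones, chosen after their values were seen, were HSD11B1 and THBD. Neutrophil and mast cell markers had 1 lower of 14, also adjusted over the list alone (median -0.51, camera adjusted p = 0.286). Complement genes had 3 higher and 7 lower of 28, 5 and 8 adjusted over the list alone (median -0.27, camera adjusted p = 0.301). The higher ones were C1QA, C1QB and C3, the last chosen after its values were seen. Keratinocyte-expressed genes had 3 of 13 lower, 2 adjusted over the list alone (median -0.88, camera adjusted p = 0.102): the cytokine IL1A fell by 2.04 ± 0.46 and the antimicrobial peptide DEFB1 by 1.84 ± 0.52, with an adjusted p of DEFB1 from 3.51e-05 to 0.0543 over the alternatives, highest with the other-organ background. Stromal and vascular genes had 1 higher and 1 lower of 19 and none adjusted over the list alone, with a median of 0.13 against a mean of -0.09 and a downward camera direction (adjusted p = 0.363). Of 5 proliferation genes none passed, over all genes or adjusted over the list alone (median -0.26, camera adjusted p = 0.585). Genes of the tumour necrosis factor and NF-kB pathway had 2 of 20 higher and none adjusted over the list alone, with a median of -0.14 against a mean of 0.07 (camera adjusted p = 0.772). TGF-beta and wound-associated genes had 1 higher and 1 lower of 10, also adjusted over the list alone (median -0.07, camera adjusted p = 0.326); the lower one was EGR1, whose healthy values were 7347 normalized counts in sample 4 and 1126 to 1419 in the others.

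Averaged into a score per sample, 10 lists were higher and 2 lower in MF by an exact two-sided permutation test over 5985 splits, adjusted over 27 lists. The T cell score was 8.64 ± 1.08 in MF (SD, n = 17) against 5.99 ± 0.33 in healthy skin (SD, n = 4), higher in 17 of 17 MF samples than in any healthy sample (exact permutation p = 0.000167, adjusted p = 0.00226). This p is the smallest the splits can give. The score of interferon-stimulated genes was 9.81 ± 0.74 against 8.47 ± 0.12 (exact permutation p = 0.00117, adjusted p = 0.00632), with 15 of 17 MF samples above the highest healthy sample. The score of interferon ligands and receptors was 4.73 ± 0.75 against 6.41 ± 0.57 (exact permutation p = 0.000501, adjusted p = 0.00451), with 15 of 17 MF samples below the lowest healthy sample. The plasmacytoid dendritic cell score was 7.20 ± 0.98 against 5.84 ± 0.22 (exact permutation p = 0.0129, adjusted p = 0.0289), and its adjusted p was 0.0671, 0.0947, 0.0581 and 0.0572 without healthy samples 1, 2, 3 and 4 in turn. Over all alternatives it ran from 0.000501 to 0.0947. The antigen presentation score passed at an adjusted p of 0.0289, and its adjusted p was 0.162 with median centring and 0.0734, 0.0987 and 0.0711 without healthy samples 2, 3 and 4 (range over the alternatives 0.0102 to 0.162). The checkpoint score was at 0.0605 and 0.05 without healthy samples 2 and 3 (range 0.000501 to 0.0605), and the score of MF-linked genes at 0.0861 and 0.0568 (range 0.000902 to 0.0861). Without healthy sample 2, and also without healthy sample 3, 8 scores passed in place of 12. MF samples 2, 5 and 9 stood apart from the other 14: their first principal component (36.7% of the variance) lay between -27.4 and -23.6, inside the healthy range of -29.4 to -20.1, against -4.46 to 25.6 in the others. Their second component (-21.4 to -15.8 against 10.7 to 25.2 in healthy skin), interferon ligand and receptor scores (3.25 to 4.71 against 5.67 to 6.95) and cancer-testis scores (2.73 to 3.27 against 5.19 to 5.86) lay below the healthy range. So did other scores, such as Th1 (4.29 to 4.59 against 5.32 to 6.01) and B cell (3.82 to 3.99 against 4.65 to 5.30). Their median gene signals, 109.5, 132.5 and 112.6 normalized counts, were the lowest of the MF samples. MF sample 6 came next at 202.7. The T cell scores of MF samples 2, 5 and 9 were 6.40 to 6.92, against 7.99 to 10.03 in the other MF samples and 5.66 to 6.38 in healthy skin. Set beside the other MF samples, their cytotoxic scores were 5.35 to 5.68 against 6.17 to 8.54, and their interferon-stimulated scores 8.44 to 8.89 against 8.83 to 10.77.

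**Figure D3:**
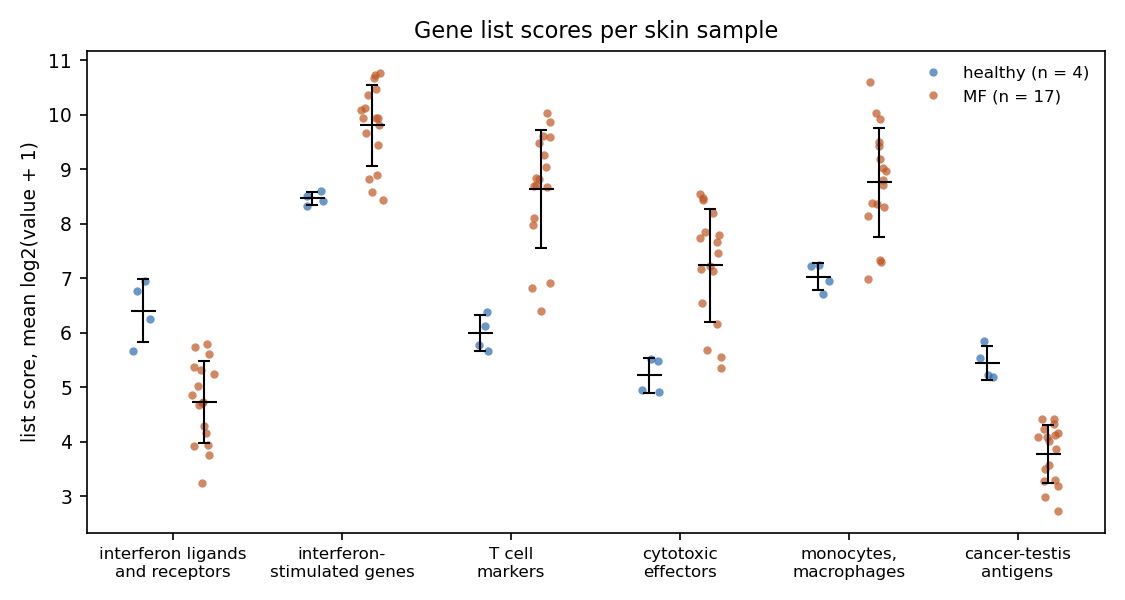
Score per sample, the mean log2(value + 1) over a list's measured genes, for 4 healthy and 17 MF skin samples (points), with the group mean and 1 SD (black lines). All 17 MF samples lie above the healthy samples for T cell markers and below them for cancer-testis antigens.

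Camera's preset correlation of 0.01 gave 9 lists higher and 2 lower, and 0 lists passed with an estimated correlation, while fry gave 9 higher and 2 lower. The healthy skin came from plastic surgery, so the source of the tissue goes with the group, and 3 MF samples carry a lower housekeeping level in the deposited values.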

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

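The tests of the weak-signal, scaling-factor and additive-background explanations, of both explanations of the immediate-early genes and of the relation with T cell score over 14 samples were chosen after the result was seen. The housekeeping-level and matched-list tests address the fall of the ligand probes, so they too were set once that fall had been seen.

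Among 117 values tested, 90 named genes and 27 list scores, 7 genes had a healthy sample far from the other 3. Chance flags about 1 in 20, so the count of 7 is near the chance rate. The gap to the nearest sample, as a share of the whole healthy range on the log2 scale, was 0.982 for MRC1 (sample 3, 305.7 normalized counts against 132.9 to 135.0), 0.932 for MAGEA1 (sample 4, 35.9 against 11.9 to 12.8) and 0.901 for IRF5 (sample 4, 46.1 against 84.0 to 89.7). It was 0.883 for PLAU (sample 3, 651 against 371 to 396), 0.879 for CD2 (sample 2, 8.01 against 21.5 to 24.5), 0.877 for EGR1 (sample 4, 7347 against 1126 to 1419) and 0.853 for CFD (sample 1, 2641 against 4423 to 4833).

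Outside the comparison, the 5 probes that only the authors' table of means holds lay above the 7.18 set by its negative controls. The authors' mean was 245.5 for IL8, 15.5 and 36.0 for the activating KIR subgroups 1 and 2, and 43.8 and 41.9 for the inhibiting KIR subgroups 1 and 2.

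The interferon ligand probes fell in MF, with a median of -2.47 over 8 ligands, and the median of the list with both receptors, -2.23, shrank to -1.06 with values below 20 set to 20 (7 ligands lower). The tables argue against the samples' scaling factors (median -2.0 on unscaled counts), the housekeeping level of MF samples 8, 9 and 10 (7 probes lower after housekeeping centring) and, as the whole cause, a single additive background (list median -1.60 and 6 probes lower after subtracting it, against -2.23 and 7 before, with an adjusted p of 0.08 for IFNA2). A weak signal shared by probes of genes that skin does not express cannot be told apart from a ligand change for most of the fall: 18 probes for genes of liver, gut, brain and other organs, of which 3 are also in the complement list, had a median of -1.84 and 15 of them fell. The ligands fell further than nearly all of 10000 random lists matched on mean level (percentile 0.02). Those lists were drawn from all other tested genes and had a median of -1.05, so they do not stand for weak probes alone. Among lists drawn from other-organ and cancer-testis probes the ligands lay at percentile 0.26. Only the latter comparison bears on a lower ligand transcription beyond the weak probes, which is a hypothesis. Near-identical interferon alpha probes make 8 ligands fewer than 8 measurements, and the source of the skin stays open.

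FOS, EGR1 and PTGS2 were higher in healthy skin. The other 12 early-response genes had a median of -1.0, with 11 of 12 negative. Of the 12, 2 were past the threshold as lower, where 99 of all 715 tested genes were. The median goes with a stress response of surgical skin before preservation, which is a hypothesis. FOS lay below the lowest healthy sample in 17 of 17 MF samples, and the disease itself cannot be told apart from handling, because all healthy skin came from plastic surgery and the source goes with the group.

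The interferon-stimulated genes may follow the amount of leukocytes in a biopsy. MF samples 2, 5 and 9 stood apart on the first principal component, with low scores of both and the lowest median gene signals of the MF samples. The relation was therefore tested over the other 14. There the interferon-stimulated score rose with the T cell score by Pearson's r = 0.66 (permutation p = 0.00995, adjusted p = 0.00995) but not past the threshold by Spearman's rho = 0.499 (permutation p = 0.0714, adjusted p = 0.0714, over 2 relations). Without the 2 samples farthest in T cell score r was 0.47 (12 samples), so the relation rests in part on those, and over the 12 samples with the common housekeeping level it was 0.67. The amount of leukocytes and a response of the skin itself to interferon cannot be told apart, because values of whole biopsies hold both.

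None of the 99 other splits drawn gave as many changed genes as the real 246 (1 of 100 splits with the real one, highest other 8). Chance is thus an unlikely source of that count if the samples are independent, which the labels do not settle. For the 11 lists passing camera chance stays open: 9 of 100 splits gave as many, the highest other 15. The other splits passed a median of 5 lists.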

How the results depend on the processing

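The alternatives with values below 20, the other-organ background, the positive control covariate and without MF samples 8, 9 and 10 were chosen after the data were seen. Causes were not tested, except that the stricter filter tests fewer genes. Changed genes were 246, from 174 to 303 on leaving out each sample, 260 by the exact Mann-Whitney test (224 shared), 447 with array weights (291 higher, 156 lower) and 146 with the replicate block (73 higher). The replicate numbers do not pair the samples: same-number deviations correlated at 0.047, 0.011, 0.385 and 0.095. In the block fit an MF sample whose number no healthy sample shares adds nothing to the comparison. That fit therefore rests on MF samples 1 to 4 against healthy samples 1 to 4. Its results are no like-for-like check on all 17 MF samples. Lower genes, 99, were 229 with median centring, 168 with quantile normalization, 41 with values above 50, 42 with the other-organ background (236 higher) and 61 to 107 on leaving out a sample, lowest without healthy sample 4. Passing scores, 12, were 19 with median centring. With an estimated correlation 0 of 11 lists passed. The medians were unchanged, at -2.23 for the list of ligands and receptors and 1.26 for the interferon-stimulated genes. With values above 50 the list of ligands and receptors had a median of -1.26 and did not pass. It then held 2 ligands, both still lower, and both receptors, so that median does not measure the ligands alone. The list's median was -1.06 with values below 20 set to 20 and -1.43 with a pseudocount of 10. The other deposited table was not run: the names of its sample columns match no label, and its means equal those used. Filters do not alter scores except above 50; weights, trend, block and covariate were not applied to scores. The chemokine list and the list linked to MF no longer passed with values above 50, nor the chemokine list with the other-organ background. Signal over background limits the weak probes.

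Directions turned mostly in lists, scores and genes that did not pass. With median centring the median of sensing genes was -0.37, of regulatory T cell genes -0.087, of B cell markers -0.45 and of stromal genes -0.58. The score differences were -0.35 for sensing (past the threshold), -0.49 for natural killer, -0.16 for B cell and -0.63 for NF-kB genes (past the threshold), and IFNAR1 was -0.61. With quantile normalization the medians were -0.30 for sensing, 0.15 for natural killer and -0.43 for stromal genes. The score differences were -0.14 for sensing and -0.46 for NF-kB genes (past the threshold), and the log2 fold changes were CXCL5 0.10, IFNL1 0.046 and IFNAR1 -0.43. With values above 50 the medians were 1.04 for natural killer, 0.045 for Th2 and 0.31 for complement genes, and the Th2 and complement scores 0.29 and 0.28. TGF-beta genes had medians of 0.0098 with housekeeping centring, 0.10 with array weights, 0.056 with the replicate block, 0.15 without MF samples 8, 9 and 10, 0.076 with the positive control covariate and 0.063 with the other-organ background. The complement score was 0.0016 with housekeeping centring, 0.068 with a pseudocount of 10, 0.0098 without MF samples 8, 9 and 10 and 0.15 with values below 20 set to 20, where the Th2 score was 0.073 and CXCL5 0.15. NF-kB genes had a median of 0.10 with array weights. With the other-organ background the medians were 2.10 for natural killer, 0.68 for Th2, 0.37 for Th17, 0.18 for neutrophil and mast cell, 0.32 for complement, 0.22 for proliferation and 0.076 for NF-kB genes. The score differences were 0.68 for Th2, 0.15 for Th17, 0.60 for neutrophil and mast cell, 0.54 for complement, 0.022 for stromal and 0.38 for proliferation genes. There the genes KIR3DL3 (0.068), CCR3 (0.57), IGLL1 (0.15), IL23R (1.25), CXCL5 (1.24), PBK (0.22) and IFNL1 (0.96) also turned, of which KIR3DL3, CCR3 and IGLL1 had passed as lower. On leaving out each sample, stromal medians ran from -0.11 to 0.19 (negative without healthy 1 or 2), NF-kB from -0.19 to 0.0044 (positive without healthy 4) and TGF-beta from -0.19 to 0.22 (positive without healthy 4 or MF 9). The NF-kB score ran from -0.067 to 0.31 (negative without healthy 2 or 3), the stromal score from -0.16 to 0.035 (positive without healthy 4) and IFNAR1 from -0.17 to 0.24 (negative without healthy 1).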

Other observations

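The test of the relation between ligand and other-organ probes was chosen after the data were seen. Across the 14 MF samples other than 2, 5 and 9, which stood apart, the mean log2 level of the 8 interferon ligand probes rose with that of 18 probes for genes of other organs (Pearson r = 0.82, permutation p = 0.00028, adjusted p = 0.00056; Spearman rho = 0.771, permutation p = 0.00203, adjusted p = 0.00406, over 2 relations). Without the 2 samples farthest in other-organ level r was 0.71, and over the 12 samples with the common housekeeping level it was 0.80. Both means carry the scaling factor of the same sample, which ranged from 0.709 to 1.98. The relation was not computed on unscaled counts, so the share due to that factor is not known.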
